A study of Mus musculus with 2 samples.

How the data were processed

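The series measured poly-A RNA of Drosha knockout mouse ES cells in 2 libraries of 1 group. Per the labels' protocols, RNA was taken with Trizol, the libraries were made with the Illumina TruSeq RNA kit, and the protocol was reverse-stranded. The deposited files hold the authors' raw read counts per Ensembl gene, 1 file per library and not pooled, per the file headers. STAR 2.4.2a, featureCounts 1.4.5-p1 and the mm10 build are named without roles or settings, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here, so counts of overlapping, antisense and near-identical genes are uncertain. Every value was a whole number, and every row was a gene, so no row was left out of the library totals.

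Gene symbols, positions, biotypes, exon lengths and GC content of the longest transcript came from GENCODE release M21 on GRCm38, the same build as mm10. Of 43629 gene IDs 97.5% matched, and the 1081 others held 0.163% of the counts. The libraries held 29264632 (A) and 42322129 (B) counts, which puts a count of 0 at no more than 0.103 and 0.0709 CPM, the level of 3 counts. Counts were scaled by TMM (edgeR 4.0.16 in R 4.3.3) and given as CPM. Lists, random draws and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

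With 1 library on each side of the comparison no replicate check is possible. Genes with at least 10 reads over both libraries were tested by a two-sided exact binomial test of the reads of B against the share expected from the scaled library sizes, with Benjamini-Hochberg adjustment and a threshold of 0.05; a second count also asked for a 2-fold difference. Log2 ratios are of B over A after adding 0.5 reads to each count. The coefficient of variation is the square root of edgeR's common dispersion. A gene counted as expressed at 1 CPM or more in both libraries. Of 20 gene lists, the median CPM was set against 10000 random lists of the same size from genes with a read, and the median log2 ratio against 10000 random lists matched on expression in 20 bins. Chromosomes were treated the same way over genes with a mean of at least 1 CPM.

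The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the detected members of the microRNA pathway, the 3 members with the highest mean CPM of each other list, the 10 most abundant genes, the 10 genes with the largest log2 ratio in each direction among called genes with at least 100 reads, the detected sex-linked markers, and Pou5f1, Sox2, Nanog, Zfp42, Klf4 and Esrrb. The list symbols Zscan4a, Dux, Mir100hg, Mir703, Mirlet7bhg and Rigi had no match under those names; Rigi is the newer name of Ddx58, which was listed too, and Cyr61 and Ccn1 are 1 gene. The alternatives were total counts and DESeq2 1.42.0 size factors as scaling, filters of 1 and 50 reads, edgeR's exact test with an assumed coefficient of variation of 0.1, thresholds of 0.5 and 5 CPM, TPM from exon lengths, random lists of expressed genes, totals without mitochondrial genes, and each library alone. Added after the data were seen were removal of the trend with GC content (20 bins, genes with at least 100 reads) and a run without Gm42418, Lars2 and Gm15564. Further lists of fibroblast, ribosomal RNA-like, Y-linked and RNA polymerase III genes serve the closing observations and were also written after the first results. The pooled ratios used there, and their limit of 5 CPM for fibroblast genes, were chosen after the first results too.

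The test was tested on simulated data: Poisson counts were drawn for the real genes at both depths, with 200 genes changed. For the comparison of the libraries, a 2-fold change was recovered in 76.5% of changed genes drawn from those with at least 10 reads, 97.0% from those with at least 100 and 100.0% from those with at least 1000. For a 1.5-fold change these shares were 65.5%, 87.0% and 100.0%, and for a 1.25-fold change 43.5%, 72.5% and 95.5%. With no gene changed 0 genes were called. A simulated GC trend, steeper than that of the libraries and opposite in sign, gave 1022 calls among 18254 genes, and 0 after its removal. The null and trend draws hold counting noise only, and the libraries differed by more. They therefore do not give the number of false calls in the real comparison. Simulated coefficients of variation of 2, 5 and 10% were estimated as 2.00, 5.13 and 10.0%. A comparison with wild-type cells was left out because the samples used here are of 1 genotype, and reads over single Drosha exons were not analysed here.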

Results

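Poly-A selected RNA was sequenced from Drosha knockout mouse embryonic stem (ES) cells, pluripotent cells derived from the blastocyst that can be kept undifferentiated in culture. The cells had the 129/Ola strain background, grew in serum with LIF, a cytokine that holds mouse ES cells in self-renewal, and were at passage 7. Drosha is the nuclear ribonuclease that cuts hairpins out of primary microRNA transcripts, the first step in making most microRNAs. There were 2 libraries, replicates A and B of 1 group, and a library of another genotype was not analysed here. The files held 29264632 gene counts for A and 42322129 for B over 43629 genes, of which 22672 had at least 1 read in A and 23567 in B. A gene with 0 reads could still have had up to 0.103 CPM (counts scaled by library size) in A and 0.0709 CPM in B, the level of 3 counts. Intervals and floors cover counting error only. The labels conflict on whether A and B are separate lines: the titles number the cells 1 and 2, while the source names are the same for both. Separate cultures are not stated, so a difference between these samples may be technical or a difference between lines. The p-values weigh it against counting error only and hold no estimate of the spread between libraries. Values are mean CPM ± SD of both libraries (n = 2), and positions are those of the GRCm38 mouse genome. A list median is the median of its members' mean CPM. The SD after it is that of the list medians of A and B taken separately, and the printed median need not lie between these.

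RNA of most genes of the microRNA machinery was present at high levels in the knockout cells. Drosha itself (ENSMUSG00000022191, chromosome 15, 12824815 to 12935291) had 4865 reads in A and 7023 in B, or 166 ± 0.378 CPM, at the 94.8th percentile of genes with a read. Its partner Dgcr8, which binds the hairpin, had 242 ± 4.20 CPM, and Dicer1, the cytoplasmic ribonuclease that makes the mature duplex, had 189.8 ± 0.646 CPM. The export factors Xpo5 and Ran had 164 ± 0.840 and 600.3 ± 13.8 CPM. The Dicer partners Tarbp2 and Prkra had 78.4 ± 2.44 and 17.8 ± 0.00942 CPM. Of the Argonautes, Ago2 was at 435 ± 0.191 CPM, Ago1 at 116 ± 2.79, Ago3 at 24.6 ± 2.23 and Ago4 at 0.994 ± 0.233. The silencing scaffolds Tnrc6a, Tnrc6b and Tnrc6c had 129.8 ± 2.71, 117 ± 1.42 and 93.8 ± 0.0493 CPM, and the RNA helicases Ddx5 and Ddx17 had 1001 ± 16.4 and 601 ± 11.6 CPM. In all, 15 of the 16 members reached 1 CPM in both libraries, with a median of 147 ± 0.933 CPM. A count over a whole gene does not show which exons were read, so the Drosha value does not check the knockout label.

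The cells had the transcripts of naive pluripotency, the state of the inner cell mass, at high levels. All 30 members of that list reached 1 CPM in both libraries, with a median of 214 ± 6.80 CPM, above all 10000 random lists of the same size. Dppa5a led the list at 2351 ± 81.6 CPM, followed by Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772) at 1179 ± 17.4 and Tdgf1 at 794 ± 19.96. The core transcription factors Sox2 and Nanog had 491 ± 2.04 and 515 ± 1.95 CPM, Esrrb 657 ± 4.81, Zfp42 629 ± 1.82 and Klf4 155 ± 5.56. Genes that switch on after implantation were partly present: 12 of 14 reached 1 CPM, led by the DNA methyltransferases Dnmt3b (277 ± 0.732) and Dnmt3a (236 ± 2.62) and by Etv4 (102 ± 0.942), whereas Fgf5, a marker of the primed epiblast, had 0.413 ± 0.0531 CPM.

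Most markers of mesoderm and of the neural and ectoderm lineage were below 1 CPM, while the other lineage lists were mixed. In the mesoderm list 4 of 14 members reached 1 CPM, with Kdr at 6.47 ± 0.441, Eomes at 3.44 ± 0.388 and Pdgfra at 1.66 ± 0.501 CPM, and the median was 0.464 ± 0.0217. Of the neural and ectoderm list 7 of 16 did, with Tubb3 at 75.9 ± 1.48, Nes at 26.8 ± 1.37 and Krt18 at 20.3 ± 0.346 CPM against a list median of 0.641 ± 0.0147. The endoderm list had 9 of 17, led by the basement membrane genes Sparc (178 ± 0.596), Lamb1 (148 ± 0.570) and Lama1 (38.3 ± 0.395), while the endoderm regulators Hnf4a, Gata4, Gata6 and Sox17 had 20.3 ± 0.577, 4.67 ± 0.576, 1.03 ± 0.0845 and 0.253 ± 0.124 CPM and the list median was 1.23 ± 0.2002. These regulators, Fgf5 and Cdx2 were chosen after their values were seen. The trophectoderm list had 7 of 12, with Tfap2c at 88.3 ± 1.01, Krt8 at 14.9 ± 0.874 and Plet1 at 14.0 ± 0.125 CPM, Cdx2 at 0.187 ± 0.0711 and a list median of 4.12 ± 0.338. The feeder fibroblast list had 8 of 15, led by Fn1 (1516 ± 7.44), Thy1 (43.3 ± 0.502) and Col5a1 (22.3 ± 0.811), with a median of 1.21 ± 0.341 CPM. Taken alone, A had 12 of its members at 1 CPM and a list median of 1.74 CPM, and B had 8 and 1.26 CPM. Only Zscan4c (1.55 ± 0.0209) among 14 matched genes of the two-cell-like state reached 1 CPM in both libraries, ahead of Zscan4d (1.02 ± 0.571) and Pramel6 (0.683 ± 0.0947), and reads of the near-identical Zscan4 copies are uncertain.

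By contrast, every one of the 16 germline genes reached 1 CPM, with Rhox5 at 149.8 ± 3.72, the receptor Kit at 139 ± 2.76 and Tex19.1 at 71.7 ± 2.37 CPM, and a list median of 27.8 ± 0.211. The medians of the lineage lists fell at the 14.3rd percentile of random lists for mesoderm, the 17.2nd for neural and ectoderm, the 32.1st for endoderm, the 33.5th for feeder fibroblast, the 56.3rd for trophectoderm, the 97.1st for post-implantation epiblast and the 97.6th for germline. These percentiles describe the libraries, are not p-values and depend on the scale. In TPM, which divides by exon length, they were 4.94 for mesoderm, 7.42 for neural and ectoderm, 10.5 for endoderm, 9.39 for feeder fibroblast, 38.8 for trophectoderm, 99.03 for epiblast and 98.1 for germline. Against random lists of genes with at least 1 CPM, mesoderm, neural and ectoderm, endoderm and feeder fibroblast lay at 0, trophectoderm at 0.350, epiblast at 55.9 and germline at 54.9.

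**Figure D1:**
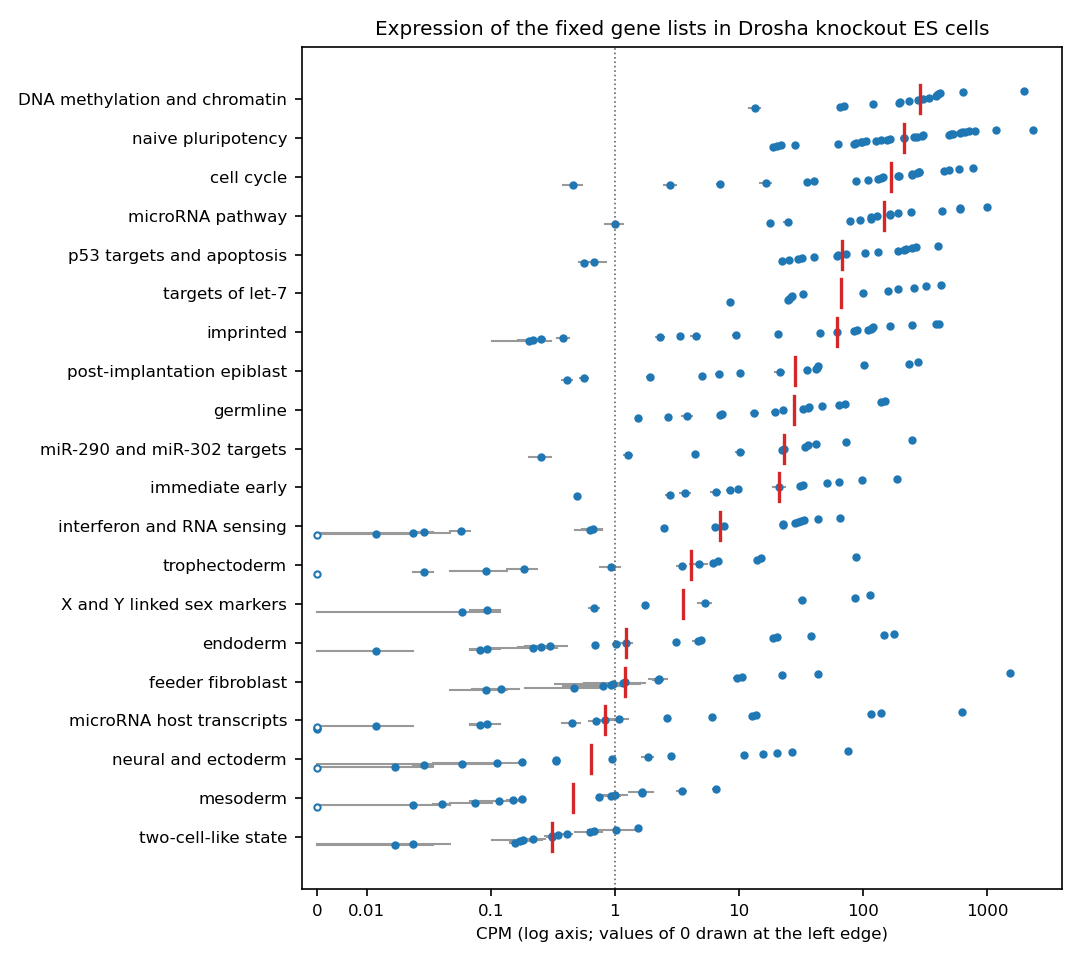
Mean CPM on a log axis of each gene in the 20 fixed lists (points, 2 libraries), with a grey line from the value in A to that in B, the list median in red and 1 CPM dotted; genes with a mean of 0 are open points at the left edge. The medians run from 0.313 CPM for the two-cell-like state to 289 CPM for DNA methylation and chromatin.

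Genes that host microRNA hairpins and the hairpins themselves were counted; a count over a host's exons measures its RNA and not the primary microRNA transcript that Drosha cuts. Of the hosts, Mcm7, whose intron carries the miR-106b to miR-25 cluster, had 627 ± 3.38 CPM, the miR-17 to miR-92a host Mir17hg (chromosome 14, 115042879 to 115046727) had 139.6 ± 0.420 and Mirg of the imprinted Dlk1-Dio3 region had 116 ± 1.78. In all 7 of 17 matched members of the host list reached 1 CPM, and the list median was 0.838 ± 0.149 CPM. The list also holds the hairpin entries Mir290a, Mir302b and Mirlet7d, and Mir290a, at 13.6 CPM, is among the 7. Of the annotated hairpins, 419 microRNA genes had at least 1 read and 34 reached 1 CPM in both libraries. The hairpins of the ES cell cluster miR-290 to miR-295 (chromosome 7, 3218626 to 3220841), singled out after the values were seen, held 53.7% of all hairpin reads in A and 51.7% in B. All 7 had at least 10 reads in each library, and they summed to 152 ± 3.38 CPM, while Nlrp12, whose annotated span covers all of them but Mir290a, had 0.700 ± 0.119 CPM. The share of hairpin reads depends on which hairpins could be given reads, since those of miR-17 to miR-92a-1, inside their host's exons, had 0. A hairpin's count is the number of reads the authors assigned to its short annotated span, so it measures longer transcripts that pass through it and not the mature microRNA.

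**Figure D2:**
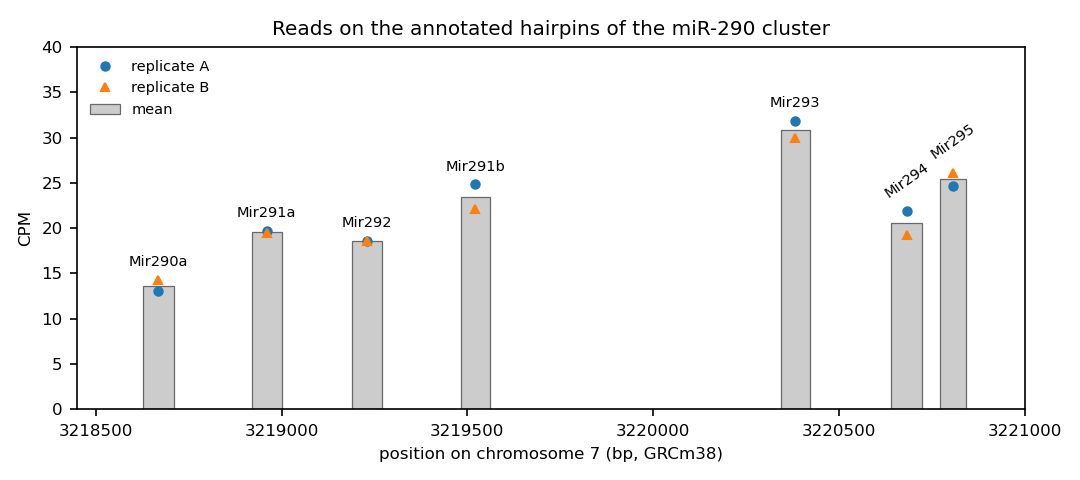
CPM of the 7 annotated hairpins of the miR-290 cluster by position on chromosome 7 (bar width, annotated span; bar height, mean of 2 libraries; circles, A; triangles, B). The means run from 13.6 CPM for Mir290a to 30.9 CPM for Mir293.

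Reported targets of the microRNAs that Drosha helps to make were expressed. All 12 reported targets of let-7 reached 1 CPM, with a median of 66.0 ± 0.354, led by Igf2bp1 (422 ± 4.43), Trim71 (323 ± 4.99) and Lin28a (257 ± 5.17). Of the reported targets of the miR-290 and miR-302 family 10 of 11 did, with a median of 22.9 ± 0.871, led by Ei24 (246 ± 3.55), the cell cycle inhibitor Cdkn1a (73.1 ± 0.000816) and Arid4b (41.4 ± 2.38). With 1 genotype, these levels say nothing of a change from wild-type cells.

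Genes of proliferation and chromatin were among the most strongly expressed groups. The cell cycle list had 21 of 22 members at 1 CPM or more and a median of 168 ± 0.865, led by Top2a (768 ± 18.7), Mcm3 (597 ± 1.68) and Cdk4 (489 ± 10.02). All 16 DNA methylation and chromatin genes did, with a median of 289 ± 2.29 CPM, led by the co-repressor Trim28 (1967 ± 52.7), Jarid2 (638 ± 1.69) and the maintenance methyltransferase Dnmt1 (414 ± 3.02). The p53 list had 16 of 18 (Trp53 at 403 ± 6.72, Trp53inp1 at 269 ± 6.31 and Ccng1 at 249.8 ± 1.87), with a median of 67.7 ± 0.576. The imprinted list had 17 of 21 (Peg10 at 409 ± 12.7, Rian at 387 ± 4.73 and Meg3 at 247 ± 6.20), with a median of 61.5 ± 1.71. The interferon and RNA sensing list had 11 of 18 and a median of 7.04 ± 0.0432 CPM, led by Adar (64.9 ± 0.0715), Ifnar1 (43.6 ± 2.37) and Ddx58 (33.5 ± 0.532), whereas Ifnb1 had 0 reads in both libraries and Isg15 had 0 and 1. The immediate early list had 12 of 13 and a median of 21.1 ± 3.37, led by Egr1 (189 ± 6.29), Ier2 (97.5 ± 4.37) and Nr4a1 (63.9 ± 2.81).

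Y-linked genes were expressed and Xist, the RNA that coats an inactive X chromosome, was low. Ddx3y had 115 ± 2.96 CPM, Eif2s3y 86.7 ± 2.88, Uty 32.3 ± 2.34 and Zfy1 1.76 ± 0.0714, while Xist had 0.683 ± 0.0947 and its antisense partner Tsix 5.34 ± 0.885. Kdm5d had 2 reads in A and 5 in B (0.0933 ± 0.0355 CPM), and Usp9y had 0 and 5. In all, 5 of 8 markers reached 1 CPM, with a median of 3.55 ± 0.478. Xist and Tsix overlap on opposite strands, and the strand setting of the counting is not given in the sources used here.

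Across the transcriptome, 13949 genes reached 1 CPM in both libraries, 12458 of them protein coding and 797 processed pseudogenes, whose reads are uncertain because they resemble their parent genes. The most abundant transcripts were the mitochondrial mt-Co1 (12678 ± 313 CPM), the translation factor Eef1a1 (10052 ± 139), the chaperone Hsp90ab1 (7690.4 ± 96.8), mt-Nd1 (5305 ± 142), Eef2 (4188 ± 51.6), Pabpc1 (4022 ± 61.4), mt-Cytb (3782 ± 83.1), the glycolytic enzyme Pkm (3679.6 ± 15.6), Rpl4 (3633 ± 47.1) and Ncl (3276 ± 155). These 10 genes took 5.83% ± 0.0763 of counts and the 100 most abundant 17.7% ± 0.185. Mitochondrially encoded genes took 2.91% ± 0.0674, the 82 ribosomal protein genes 3.29% ± 0.0425 and the 67 replication-dependent histone genes, whose mRNAs end without a poly-A tail, 0.00271% ± 0.000193.

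Both libraries were then compared gene by gene. Few genes differed much: 16 of 18198 genes with at least 10 reads were called with a difference of at least 2-fold, 11 higher in A and 5 higher in B. Fibroblast matrix genes stood out among those higher in A. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), a fibrillar collagen, had 47 reads in A and 14 in B, a log2 ratio of B over A of -2.24 (adjusted p = 3.37e-06, two-sided exact binomial test, Benjamini-Hochberg). In the same test Postn, a matrix protein of connective tissue, had a log2 ratio of -1.93, the collagen Col1a2 -1.67 and the proteoglycan Dcn -1.60, with Benjamini-Hochberg adjusted exact binomial p of 0.0312, 0.00506 and 0.000437. The others higher in A were Tmem238, Otop1, Pmfbp1, A730011C13Rik, Gm17690, Gm28719 and the pseudogene Rpl31-ps13. Higher in B were Adm, Rn7sk, D130040H23Rik, Mir3070a and Scg2, which had 0 reads in A and 16 in B. Set against the floor of A, Scg2 was 3.71-fold higher in B. That value leaves out the counting error of B, so it is not a lower limit. Genes outside the naming rule in these counts were named after their values were seen. The count of 16 was 9 with a filter of 1 or of 50 reads and 7 with the trend with GC content removed. Under edgeR's exact test with an assumed coefficient of variation of 0.1 only Col3a1 was called. The assumed variation is larger than the 2.26% estimated between these libraries.

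Among called genes with at least 100 reads, the largest log2 ratios lower in B were those of Tmem238 (-1.02), Dlec1 (-0.84), Gm15832 (-0.72), Slc34a3 (-0.68), the pseudogene Rps2-ps10 (-0.67), the antisense RNA Nespas (-0.54), Ier5l (-0.53), Gm10651 (-0.47), Tpgs1 (-0.46) and Nudt22 (-0.43). Higher in B were Lrrn4cl (0.83), Gm12013 (0.80), Ccdc85a (0.72), Rps27a-ps2 (0.60), Ccdc125 (0.58), BC005561 (0.51), Dpm1 (0.51), Gm15564 (0.46), Gm14401 (0.45) and Lars2 (0.44). Lars2 (chromosome 9, 123366927 to 123462666) had 297 CPM in A and 403 in B, with an adjusted p of 1.64e-118 in the exact binomial test with Benjamini-Hochberg adjustment. Of these genes 4 are annotated as pseudogenes and Nespas and Gm15564 as antisense RNAs, so their reads are uncertain.

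In the fixed lists 16 members were called over all genes. Of the feeder fibroblast list 4 were called over all genes and 4 when adjusted over the list alone. The naive pluripotency list had 4 and 8, with Utf1 (-0.22) and Klf2 (-0.14) lower in B and Dppa5a (0.071) and Tdgf1 (0.051) higher. The cell cycle list had 2 (Top2a, 0.050, and Ccnd3, -0.076) and 6 adjusted over the list alone, the chromatin list 2 (Trim28, -0.055, and Suz12, 0.058) and 3, and the microRNA pathway 1 (Ran, 0.047) and 4. Junb (-0.33) was the call of the immediate early list, which had 3 adjusted over the list alone, Peg10 (0.063) that of the imprinted list and Sesn2 (-0.089) that of the p53 list, with 1 each adjusted over the list alone. The trophectoderm, two-cell-like and interferon lists had 0 calls over all genes and 1 each over the list alone, and the other lists had 0 in both counts. As a group, 9 of 13 tested fibroblast genes were lower in B, with a median log2 ratio of -0.19 that lay at the 0.270th percentile of 10000 random lists of like expression. The immediate early median was -0.090, at the 0.575th percentile, and the medians of the other 18 lists lay between the 2.5th and 97.5th. With the trend with GC content removed, the immediate early median shrank to -0.035, at the 10.2nd percentile. The median of the microRNA host list, hairpin entries included, then went from 0.031 to 0.092, at the 97.9th. A filter of 1 read alone put the host list at 0.14 and the 99.3rd.

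**Figure D3:**
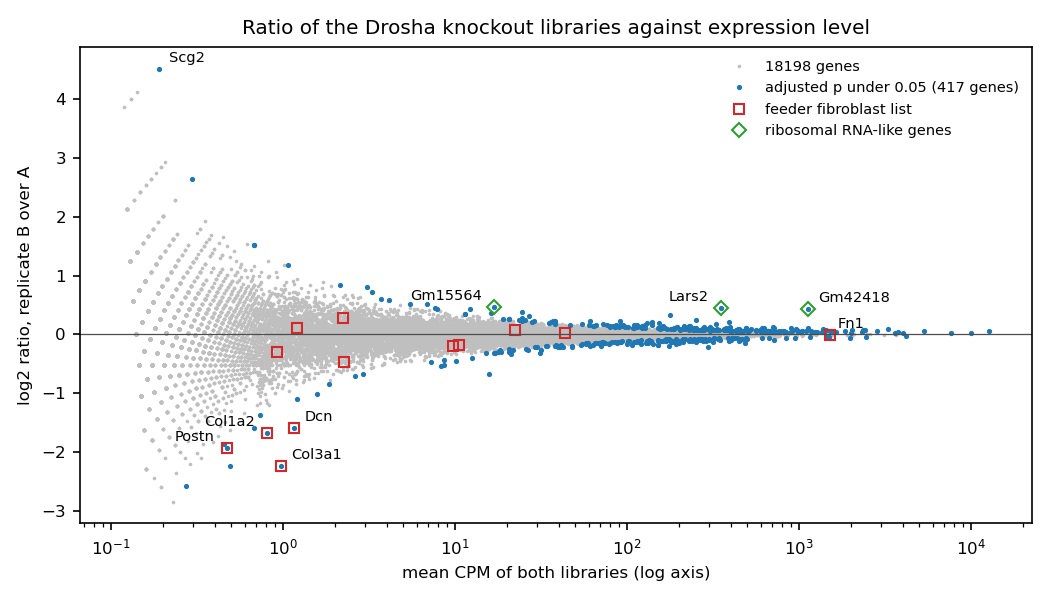
Log2 ratio of replicate B over A, after adding 0.5 reads to each count, against mean CPM on a log axis for 18198 genes; blue points are the 417 genes with an adjusted p under 0.05, squares the feeder fibroblast list and diamonds Gm42418, Lars2 and Gm15564. Col3a1 lies at -2.24 and Lars2 at 0.44, while Fn1, the most abundant gene of the fibroblast list, lies at -0.010.

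With no size rule 417 genes were called by the exact binomial test with Benjamini-Hochberg adjustment, 237 higher in B and 180 higher in A. Scaling by total counts in place of TMM gave 180 higher in B and 242 higher in A, since a shift of -0.0073 in every log2 ratio moved 57 genes higher in B out of the calls and 62 higher in A into them. The libraries were close: the Pearson correlation of log2 CPM across 13949 genes, which are not independent replicates, was 0.998, and 96.0% of these genes differed by less than 1.25-fold. They still differed by more than sampling noise, with a chi-square of 37788 over 18198 genes and a coefficient of variation of 2.26% beyond counting error, a spread that includes the GC trend and does not tell separate cultures from repeat preparations of 1 culture. The labels name them as replicates A and B, so n counts 2 libraries. The ratio followed GC content across genes: its median went from 0.039 in the 20% of genes with the lowest GC content to -0.055 in the 20% with the highest. With that trend removed, an alternative chosen after the data were seen, 144 genes were called, 122 of them among the 417. The 4 fibroblast genes, Utf1 (from -0.22 to -0.14), Dppa5a (from 0.071 to 0.062), Lars2, Gm15564, Rps2-ps10, Nespas, Ier5l and Gm12013 kept an adjusted p under 0.05.

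Removing the GC trend moved each named log2 ratio by at most 0.083, so small ratios lost a larger part than large ones. Of the list members Klf2, Tdgf1, Top2a, Ccnd3, Suz12, Trim28, Ran, Junb, Peg10 and Sesn2, which lost their calls, 5 of 10 had an interval without 0 afterwards. Junb went from -0.33 (95% exact binomial interval -0.48 to -0.18) to -0.24 (-0.39 to -0.095), Klf2 from -0.14 (-0.18 to -0.090) to -0.054 (-0.10 to -0.0070), Peg10 from 0.063 (0.030 to 0.097) to 0.051 (0.018 to 0.085) and Ran from 0.047 (0.019 to 0.075) to 0.035 (0.0068 to 0.063). Top2a went from 0.050 (0.025 to 0.074) to 0.020 (-0.0042 to 0.045) and Trim28 from -0.055 (-0.070 to -0.039) to 0.0061 (-0.0092 to 0.021). Of the 10 most abundant genes all but Pkm were called, and Eef1a1, Hsp90ab1, Ncl and Rpl4 stayed so. The calls of mt-Nd1, Pabpc1, mt-Cytb, mt-Co1 (from 0.050 to 0.0045, interval -0.0016 to 0.011) and Eef2 (from -0.025 to 0.019, interval 0.0084 to 0.029) were lost. The 14 genes named for large ratios that lost their calls all had an interval without 0 afterwards, such as Tmem238, from -1.02 (-1.61 to -0.44) to -0.93 (-1.53 to -0.36), and Lrrn4cl, at 0.83 (0.33 to 1.37) both times. Those intervals could hardly have reached 0: the genes were chosen for large ratios and small p, and the shift was at most 0.083. The intervals are not adjusted for that choice. With fewer genes called the Benjamini-Hochberg adjustment is stricter, and 7 of these 14 still had an unadjusted exact binomial p within the largest called in the main test, 0.00114. The test compares these libraries and not conditions.

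No chromosome differed by much between the libraries. Chromosome medians of the log2 ratio over genes with at least 1 CPM ran from -0.0195 on chromosome 7 to 0.0216 on the X chromosome, leaving out Y with 9 genes at -0.060. Although 12 of 20 chromosomes lay outside the 2.5th to 97.5th percentile of random lists of like expression, removing the GC trend left chromosome 5, at -0.0076, as the only one outside.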

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

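The tests with the GC trend removed and without the ribosomal RNA-like genes were chosen after the data were seen. No paired analysis was possible because there is 1 group. The count of 417 differing genes stayed between 360 and 441 under the other scalings, the read filters and without the ribosomal RNA-like genes. It fell to 144 with the GC trend removed. With edgeR's exact test and an assumed coefficient of variation of 0.1 it was 1 (Col3a1). That assumed variation is larger than the 2.26% estimated between these libraries. The count of at least 2-fold differences, 16, was 9 with a filter of 1 read, 9 with 50 reads, 7 with the GC trend removed and 1 under the assumed variation; the higher filter tests fewer low genes. Of the 9 lost with the GC trend removed 8 kept a ratio of at least 2-fold, and no ratio moved by more than 0.083 log2, so the adjusted p ended these calls; the cause of the other changes was not tested. Members at 0.5 CPM numbered 7 for mesoderm and 3 for the two-cell-like state, and at 5 CPM 1 for mesoderm, 0 for the two-cell-like state, 5 for endoderm, 5 for feeder fibroblast and 3 for sex markers. Either library alone gave 1 to 2 two-cell-like genes. The fibroblast median was -0.306 with a filter of 1 read and kept its sign in all 5 alternatives; the immediate early median was -0.0348 with the GC trend removed, at the 10.2nd percentile. Removing the trend brought the largest chromosome median to 0.00776 and turned the sign for 5 of the 12 chromosomes outside the random range, 3 (-0.00133), 6 (-0.000999), 13 (-0.00363), 15 (0.000419) and 17 (8.34e-06), and for 7 of those inside it. The median of the microRNA host list, hairpin entries included, was 0.0922 with the trend removed (97.85th percentile) and 0.136 with a filter of 1 read (99.34th). With mitochondrial genes left out of the totals, ribosomal protein genes took 3.384%, the 10 most abundant genes 3.764% and the 100 most abundant 15.34%. The 5 alternatives for the 13949 expressed genes and 3 for the coefficient of variation moved them by less than 1.5 times. Depth limits the calls: the recovery of a 1.25-fold change in simulated counts was 43.5% from 10 reads and 95.5% from 1000.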

Other observations

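MicroRNA clusters differed widely in how many reads fell on their hairpins. Next to the miR-290 to miR-295 cluster at 152 ± 3.38 CPM (SD, n = 2), the X-linked miR-106a to miR-363 cluster had 12.2 ± 0.608 CPM with all 6 hairpins at 10 reads or more in both libraries, the Dlk1-Dio3 region on chromosome 12 had 14.6 ± 0.956 CPM with 14 of 48 hairpins at that level, and miR-23b with miR-27b on chromosome 13 had 4.96 ± 0.417 CPM. The miR-302b to miR-367 cluster had 0 reads in A and 1 in B. The 6 hairpins of miR-17 to miR-92a-1 had 0 reads in both libraries although their host Mir17hg had 139.6 ± 0.420 CPM; they lie inside its annotated exons, where a read belongs to a pair of genes at once, so this 0 says nothing of the transcript. Hairpin genes outside these clusters with high counts included Mir692-1 at 23.3 ± 0.570 and Mir5125 at 4.56 ± 0.686 CPM.

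The germline genes beyond the leading ones were spread over a wide range. Dmrt1 had 64.1 ± 1.00 CPM, Sycp3 46.4 ± 2.12, Stra8 36.7 ± 1.68, Mael 36.1 ± 0.4004, Piwil2 32.8 ± 0.314, Ddx4 22.8 ± 0.736 and Dazl 13.3 ± 1.29, while Tex101 had 1.55 ± 0.0209 (SD, n = 2). Imprinted genes of the Dlk1-Dio3 region ranged widely: Rian, Meg3 and Mirg had 387 ± 4.73, 247 ± 6.20 and 116 ± 1.78 CPM, and Dlk1 and Rtl1 had 2.33 ± 0.257 and 0.219 ± 0.0756. H19 and Igf2 on chromosome 7 had 0.384 ± 0.0605 and 3.34 ± 0.0987 CPM.

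The patterns below were noticed in the data, so each explanation is a hypothesis; the tests on histone and RNA polymerase III transcripts, on the exons of Kdm5d and on its Y-linked neighbours were chosen after the results they measure had been seen. Apart from a trace of fibroblasts and loss of the Y chromosome, no biological explanation was tested, since there is 1 group.

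The 8 fibroblast genes under 5 CPM were together lower in B than in A, with a pooled log2 ratio of -0.62 (95% exact binomial interval -0.84 to -0.40). The limit of 5 CPM was set after the list's lower ratios in B had been seen. The pooled ratio therefore measures the same pattern again and is not a new test of it. Of these, Col3a1, Col1a2, Dcn and Postn were called, while Col1a1, Col6a1, Fbn1 and Acta2 were not and had -0.087 (-0.36 to 0.18). The calls made this split, so the uncalled genes were bound to lie nearer 0. It does not show which genes carry the shift. The 5 more abundant members, Fn1 among them at 1516 CPM, had -0.010. The GC trend is too small to account for the lower pooled ratio of the 8 genes: with the trend removed it was -0.605 (-0.82 to -0.39). Its removal moved no named log2 ratio by more than 0.083, so this interval could hardly have reached 0. A trace of fibroblasts in A may be the source, although the labels name no feeder cells: a second list of 40 fibroblast genes, whose 15 members under 5 CPM include Col6a2, Mfap5 and Loxl1, gave -0.0783 (-0.21 to 0.054), above the bound of -0.3 set beforehand to rule a trace out. That bound was judged wrong after the value was seen, because the second list's own level in B was 26.2 CPM. In A, Col3a1, Col1a2, Dcn and Postn together exceed B by 3.85 ± 0.465 CPM (counting error). They were picked for being called higher in A, so this excess may be too large, and the second list need not share it. An equal excess would move the second list by -0.20, just inside its interval, whereas its own excess was 1.46 ± 1.25 CPM. The second list therefore neither shows nor excludes a trace of that size. The 12 members with 1 to 9 reads had -0.940 (-1.91 to 0.0024), too few reads to decide, so a trace of other cells, differentiation of a few cells and RNA from another library remain open.

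Gm42418, Lars2 and Gm15564, which hold sequence like ribosomal RNA, were higher in B, with a pooled log2 ratio of 0.43 (0.41 to 0.45). The GC trend is argued against as the cause, since its removal left 0.494 (0.48 to 0.51). Removal moved the ratio of Gm42418 by 0.083 and those of Lars2 and Gm15564 by less, so the interval could hardly have reached 0. More RNA without a poly-A tail in general was tested on the replication-dependent histone genes. They had -0.138 (-0.27 to -0.0060) where a ratio above 0.2 was needed. Their reads were few, 832 in A and 1088 in B, and whether these come from mRNAs without a tail was not tested. The value therefore shows no rise of histone transcripts and cannot exclude more of other RNA without a tail. RNA polymerase III transcripts (Rn7sk, Rmrp, Rpph1, Rn7s1 and Rn7s2) had 0.620 (0.27 to 0.98), which could point to more structured non-coding RNA carried into B, but without Rn7sk, already known to be higher in B, the ratio was 0.46 (0.083 to 0.84) and the interval reached below 0.2. However, snoRNA genes took 0.0275% of counts in A and 0.0276% in B, and snRNA genes 0.000957% and 0.000988%. Genes annotated as miscellaneous RNA, Rn7sk among them, took 0.000393% in A and 0.000610% in B, and ribozymes 0.000321% and 0.000428%. Genes annotated as ribosomal RNA took 0.000270% in A (79 reads) and 0.000284% in B (120 reads). The 2 mitochondrial ribosomal RNAs had a pooled log2 ratio of 0.108 (0.087 to 0.129), with the GC trend not removed. A rise over all structured non-coding RNA is therefore not shown. The source of the difference stays open.

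Kdm5d (chromosome Y, 897788 to 956786), a histone demethylase gene, had 7 reads in all, while Uba1y, Eif2s3y, Uty and Ddx3y near it had 11.2, 86.7, 32.3 and 115 CPM and Usp9y (1298961 to 1459782), beyond Ddx3y, was as low with 0 and 5 reads. Loss of the whole Y chromosome does not account for this, since it would lower these genes alike and the lowest of the 4 expressed ones was 55.7 times the upper 95% limit of Kdm5d, 0.202 CPM; whether some cells lost it is not decided. Reads lost to near-identical sequence are argued against, since 4% of the 50-base words of its longest coding transcript occur in another gene against 48.9% for Uba1y, and 0% of its exonic bases lie in exons of another annotated gene. A single deletion over both Kdm5d and Usp9y is argued against, since Eif2s3y, Uty and Ddx3y, which lie between them in the reference genome, were expressed. Low transcription of Kdm5d and Usp9y in ES cells, separate local deletions and a strain variant remain open and were not tested.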
